A study of Mus musculus with 20 samples.

How the data were processed

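Gene expression was measured on 20 Affymetrix mouse arrays hybridised with amplified, biotin-labelled RNA from cells sorted from bone marrow. The labels assign the arrays to 9 groups. The authors' deposited table holds 1 intensity per probe set and array on a linear scale, for 45101 probe sets. Per the submitters' processing notes these intensities were produced with RMA, a method that corrects background, normalizes between arrays and summarises probes. Its version is not given in the sources used here. The test design had assumed RMA values on the log2 scale. Because the deposited values were linear intensities, their log2 was taken first and nothing else was changed. Array medians lay between 3.78 and 4.04 on the log2 scale. No replicate pair held identical columns.

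Gene names came from the platform table given for these probe sets. In it 34958 probe sets had 1 gene symbol, 932 had several, and 9211 had none here. Of the probe sets with 1 symbol, 34754 were matched by Entrez ID to a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names and gene order only. Genes were named from single-symbol probe sets, each gene by its probe set of highest mean over the 20 arrays, which left 18193 genes. A gene was tested when it lay above the array median on at least 2 arrays. That kept 13478 genes and left out 4715 as dim.

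Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) in 1 model over the 20 arrays and 9 groups, with 11 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and genes were called at an adjusted p below 0.05. Fold changes are given on the log2 scale with the standard error (SE) of the moderated model, and group levels as mean log2 intensity with the standard deviation (SD). Fixed gene lists, 23 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which took no intensity trend, each adjusted over the lists. Values of fry are given here only for identity genes, not for the fixed lists. Identity genes of a population lay at least 1 log2 unit above each of the other 7 populations, with each contrast called. For NK cells the mean of both genotypes was used, whose estimate has an error independent of that of the contrast between them. Both rest on the same pooled error per gene, and a gene high in 1 genotype alone can pass through the mean.

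Comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for the NK genotypes, Ets1, the 10 largest changes in each direction, and up to 4 called members of each list, or the 2 largest with their values where none was called. For the other comparisons it took the 3 largest changes in each direction and up to 4 called members of lists that name a population compared. For identity genes it took the 5 with the largest margin, and for the ETS family the members of highest level, which are not given because levels of different probe sets are not comparable. Unnamed gene models and antigen receptor segments were left out unless they were list members. Some list members were not analysed here.

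The method was tested on simulated data made from the real group means and residual spread of all 13478 genes for the contrast of the NK genotypes. Over 20 simulations with 200 changed genes, 22.7% of genes changed by 1 log2 unit and 84.0% of those changed by 2 log2 units were recovered, and 4.90% of the calls were false. A list of 30 genes shifted by -0.5 log2 units was detected in 100% of simulations. These simulated genes were independent of each other, which real list members are not. Their noise was normal with 1 SD per gene for all groups, as the model assumes. Real root-mean-square SDs ran from 0.171 in GMP to 0.561 in CLP, so recovery and false calls under unequal spread were not tested.

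The alternatives were no filter or a stricter filter on dim genes, the mean of a gene's probe sets or every probe set on its own, no intensity trend, repeated quantile normalization, centring on housekeeping genes, fits on the compared arrays alone, the replicate number as a block, array weights, a 2-fold threshold, and leaving out each replicate. The use of CLP array 2 as the single CLP array, also with ProB array 2 as the single ProB array, was added after the data had been seen. The number of arrays, 2 or 3 per group, limits the precision. Leaving out an array also enlarges the error of its contrast, so a call can end while the estimate hardly moves. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which can be technical.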

Results

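Expression profiles were obtained from 20 arrays of cells sorted from the bone marrow of mice aged 8 to 14 weeks. The wild-type C57bl/6 series covered hematopoietic stem cells (HSC, n = 2), multipotent progenitors (MPP, n = 2), lymphoid-primed multipotent progenitors (LMPP, n = 2), common lymphoid progenitors (CLP, n = 3), granulocyte-monocyte progenitors (GMP, n = 3), pro-B cells (n = 2) and CD4 T cells (n = 2). Mature natural killer (NK) cells came from mice of the 129 strain deficient for Rag2, a gene needed for antigen receptor rearrangement, with Ets1 present (n = 2) or deficient (n = 2). Replicate arrays correlated at 0.918 to 0.997 across the 13478 genes tested. CLP arrays 1 and 3 stood apart, with actin 3' signal above 5' signal by 5.20 and 5.27 log2 units against 3.26 in CLP array 2. The same ratio was 6.44 to 6.68 in GMP. Root-mean-square SD per gene was 0.561 in CLP and 0.191 in Ets1-present NK cells, and the model used 1 pooled error for all groups.

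Ets1 encodes the founding member of the ETS transcription factor family, and its level was examined first. On its probe set of highest mean Ets1 was highest in Ets1-present NK cells (11.40 ± 0.07, SD, n = 2), Ets1-deficient NK cells (11.07 ± 0.31, n = 2) and CD4 T cells (10.99 ± 0.07, n = 2), intermediate in pro-B cells (9.30 ± 0.23, n = 2) and CLP (8.18 ± 1.03, n = 3), and lowest in HSC (5.76 ± 0.21, n = 2). Ets1 rose from LMPP to CLP by 1.27 ± 0.38 (SE, adjusted p = 0.0207), although CLP array 3 (6.99) lay within the LMPP arrays (7.02 and 6.82) and another probe set had means of 4.12 in LMPP and 4.17 in CLP. It was 3.21 ± 0.38 higher in NK cells than in CLP (adjusted p = 2.02e-06). Between the NK genotypes its 4 probe sets differed by -1.55 ± 0.31 (adjusted p = 0.00865), -0.93 ± 0.29 (adjusted p = 0.118), -0.33 ± 0.42 (adjusted p = 0.981) and -0.81 ± 0.54 (adjusted p = 0.756), adjusted over all 45101 probe sets. Signal remained on each probe set in the Ets1-deficient arrays. Where these probes lie relative to the deletion was not analysed here, so the signal does not check the genotype labels. Between the NK genotypes limma called 0 of the 22 ETS family genes tested, against 1 at an unadjusted p below 0.05 (camera adjusted p = 0.825). The largest differences were 1.01 ± 0.39 for Ets2 (adjusted p = 0.206) and 0.63 ± 0.61 for Etv5 (adjusted p = 0.842).

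**Figure D1:**
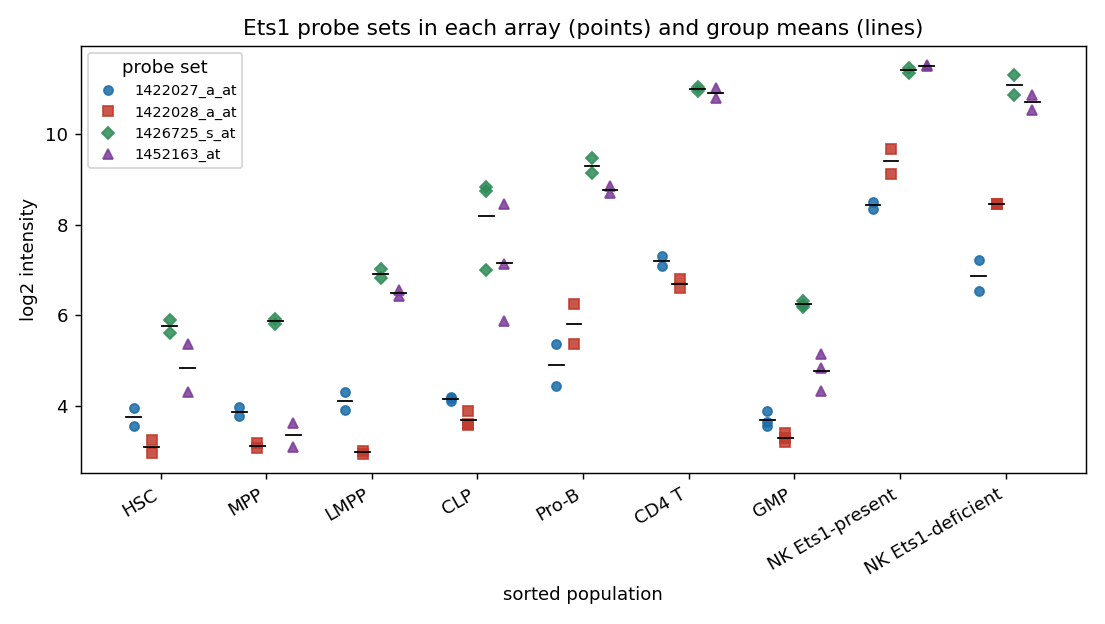
Log2 intensity of the 4 Ets1 probe sets (colours and symbols) in each sorted population; points are arrays and lines are group means. On the 2 probe sets with the highest means Ets1 was highest in NK and CD4 T cells, and all 4 probe sets kept signal in the Ets1-deficient NK arrays.

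The stated aim of the series was to find genes that depend on Ets1 in NK cells. In the Ets1-deficient NK arrays Ltb, Il7r and Xcl1 were lower, as were myeloid genes and activating receptor genes as lists. Gzmb, a granzyme of cytotoxic granules, and the CD3 chains Cd3g and Cd3d were higher. In all, 214 genes were higher and 300 lower among 13478 tested (n = 2 per genotype), with 1743 genes at an unadjusted p below 0.05. The arrays of the genotypes did not overlap for 55.4% of all genes tested, where chance gives 33.3%. The largest rises were in Dixdc1 (7.06 ± 0.35, SE, adjusted p = 3.3e-10), a Wnt pathway gene, and Scel (5.37 ± 0.26). They were followed by Apcdd1 (4.77 ± 0.42), Tubb2b (4.40 ± 0.27), Mreg (4.35 ± 0.32), Cd3g (3.96 ± 0.25), Khdc1a (3.51 ± 0.20), Garem1 (3.44 ± 0.41), Ccdc88a (3.30 ± 0.39) and Cdhr1 (3.28 ± 0.31). The largest falls were in Vegfc (-5.19 ± 0.51, adjusted p = 2.98e-06), a lymphatic growth factor, and Ltb (-4.71 ± 0.38, adjusted p = 2.09e-07), which encodes lymphotoxin beta. Btbd11 (-3.83 ± 0.39), the collagen receptor Lair1 (-3.77 ± 0.29), the neutrophil enzyme Mpo (-3.59 ± 0.40), Rgl1 (-3.52 ± 0.44), Acpp (-3.27 ± 0.29), Dmrta1 (-3.23 ± 0.18), Slfn2 (-3.22 ± 0.24) and Gprin3 (-3.11 ± 0.44) also fell. The order rests on the choice of probe set: with the mean of a gene's probe sets Dixdc1 was 2.46, Scel 2.61, Apcdd1 1.40, Garem1 1.65 and Ccdc88a 1.48. Lair1 was then -1.86, Rgl1 -1.82, Acpp -1.24 and Gprin3 -1.56, and these 9 genes were still called. Leaving out 1 of the 2 arrays of a genotype enlarges the error of the contrast. A call lost in that way does not by itself show that the change hung on the array. Of 60 called genes that the fixed rule took from this contrast, 24 lost their call under an alternative, 23 of them when 1 array was left out.

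**Figure D2:**
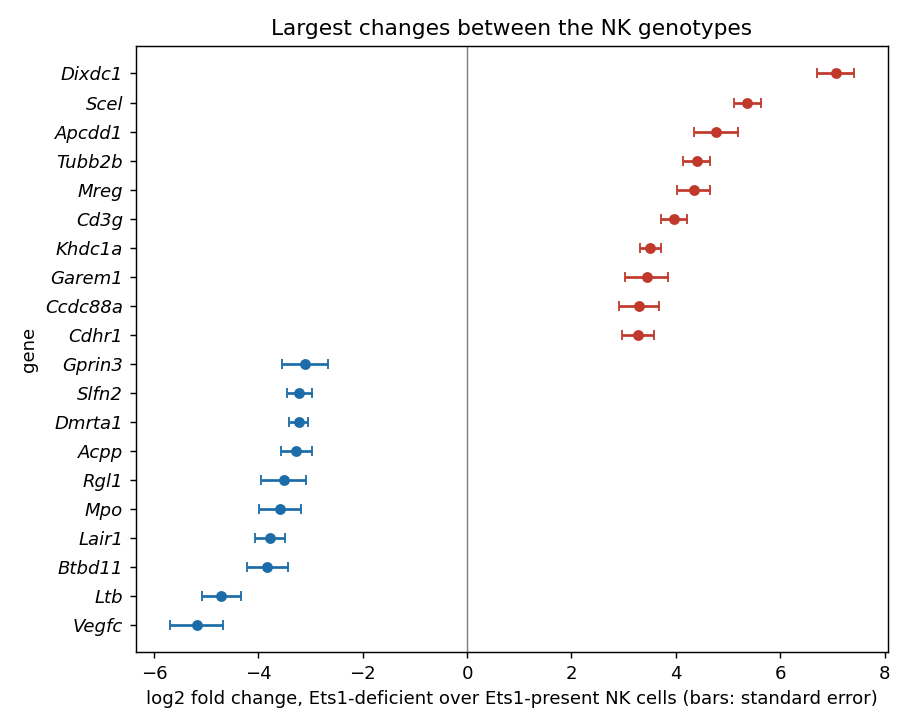
Log2 fold change of the 10 genes with the largest called rise and the 10 with the largest called fall in Ets1-deficient against Ets1-present NK cells; points are estimates and bars are standard errors (n = 2 arrays per genotype). Dixdc1 rose by 7.06 log2 units and Vegfc lay at -5.19.

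Activating NK receptors and adaptors were lower as a list, with 4 of 15 members down and 11 not passing (6 down adjusted over the list alone). They were Klrb1f (-2.35 ± 0.62), Crtam (-2.16 ± 0.42), which binds a nectin-like ligand, Slamf6 (-1.58 ± 0.35) and the Fc receptor Fcgr3 (-1.22 ± 0.30). The list passed camera at adjusted p = 2.2e-06, and at adjusted p = 0.0154 with an estimated correlation. Its called members numbered 0 without Ets1-present replicate 1, 1 without Ets1-present replicate 2 or Ets1-deficient replicate 2 and 2 without Ets1-deficient replicate 1. Klrb1f and Fcgr3 lost their call whichever of the 4 arrays was left out (-2.16 to -2.54 and -1.15 to -1.30), and Crtam without Ets1-present replicate 1 (-2.07). Klrb1f was also not called after repeated quantile normalization (-2.38). Slamf6 lost its call without Ets1-deficient replicate 2 (-1.24), Ets1-present replicate 1 (-1.55) or Ets1-present replicate 2 (-1.61), and with the mean of its probe sets (-0.62). Inhibitory receptors went both ways, with 3 of 13 up and 2 down (3 and 5 adjusted over the list alone, camera adjusted p = 0.652). Klra5 (2.79 ± 0.30), Pdcd1 (2.19 ± 0.21), which encodes PD-1, and Klrg1 (1.75 ± 0.31), a marker of mature NK cells, rose, and Lair1 and Klra17 (-2.01 ± 0.29) fell. Klra genes form a family of close copies, so their probe sets can cross-hybridise and these values are uncertain. Among 24 cytotoxic effectors and cytokines, Gzmb (2.67 ± 0.36) and Gzmk (1.45 ± 0.33) rose and the chemokines Xcl1 (-2.50 ± 0.26), Ccl3 (-1.84 ± 0.50) and Ccl4 (-1.56 ± 0.36) fell (3 up and 5 down adjusted over the list alone, camera adjusted p = 0.597). This list had 1 up and 1 down without Ets1-present replicate 1 or 2, 2 up and 2 down without Ets1-deficient replicate 1, 1 up and 3 down without Ets1-deficient replicate 2, 1 up and 3 down after centring on housekeeping genes and 2 up and 1 down after repeated quantile normalization. Ccl3 and Ccl4 lost their call without Ets1-deficient replicate 1 (-1.19 and -1.39), without Ets1-present replicate 2 (-1.97 and -1.62), without Ets1-present replicate 1 (-1.70 and -1.51), and after repeated quantile normalization (-1.79 and -1.42). Gzmk, chosen after its values were seen, lost its call without Ets1-deficient replicate 2 (1.27), Ets1-present replicate 1 (1.46) or Ets1-present replicate 2 (1.44) and after centring on housekeeping genes (1.21). Ccl3 was also not called with no filter on dim genes (adjusted p = 0.0553), with every probe set on its own (adjusted p = 0.0512) or after centring on housekeeping genes (-2.08, adjusted p = 0.0521).

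Cytokine receptor and JAK-STAT genes were lower as a list at camera adjusted p = 0.00101, which was adjusted p = 0.158 with an estimated correlation. Of its 36 members, Il7r (-2.59 ± 0.43), the interleukin-7 receptor, Il6st (-1.81 ± 0.29) and Kit (-1.81 ± 0.49) fell and Socs2 (2.89 ± 0.42), a feedback inhibitor of cytokine signalling, rose. Trafficking, adhesion and maturation genes had 4 of 32 members down and 1 up (camera adjusted p = 0.029, and adjusted p = 0.122 with an estimated correlation). Cd44 (-2.21 ± 0.27), Cd27 (-1.77 ± 0.32), a marker of less mature NK cells, Icam1 (-1.53 ± 0.31) and Thy1 (-1.50 ± 0.32) fell, and the integrin Itga1 (1.63 ± 0.38) rose. Interferon-stimulated genes had 4 of 31 members down and 27 not passing (camera adjusted p = 0.00104, and adjusted p = 0.424 with an estimated correlation). These were Ifit1 (-1.50 ± 0.35), Rtp4 (-1.46 ± 0.32), Irf9 (-1.27 ± 0.32) and Xaf1 (-1.21 ± 0.31). Counts adjusted over the list alone were 1 up and 6 down for the cytokine receptors, 4 up and 7 down for trafficking and 1 up and 7 down for interferon-stimulated genes. After centring on housekeeping genes trafficking genes had 0 up and 6 down. Thy1, chosen after its values were seen, was not called without Ets1-deficient replicate 2 (-1.40), Ets1-present replicate 1 (-1.61) or Ets1-present replicate 2 (-1.39). Without Ets1-present replicate 1 or 2 trafficking genes had 0 up and 2 down and interferon-stimulated genes 0 called. Without Ets1-deficient replicate 1 trafficking genes had 0 up and 4 down, without replicate 2 they had 2 up and 4 down, and without either 2 interferon-stimulated genes were down. Kit and Irf9 lost their call whichever array was left out (-1.63 to -1.99 and -1.05 to -1.49). Without Ets1-deficient replicate 1, Itga1 (0.77), Icam1 (-1.36) and Ifit1 (-1.17) were not called, and without Ets1-deficient replicate 2, Rtp4 (-1.36) and Xaf1 (-0.83) were not, while Itga1 was 2.49. Without Ets1-present replicate 1 or 2, Itga1 (1.57 and 1.69), Icam1 (-1.61 and -1.46), Ifit1 (-1.63 and -1.36), Rtp4 (-1.55 and -1.37) and Xaf1 (-1.05 and -1.38) lost their calls. The mean of a gene's probe sets ended the calls of Kit (-0.86), Itga1 (0.90) and Il6st (-0.59), and gave values over 1.5 times smaller for Il7r (-1.40), Socs2 (0.99), Cd44 (-1.05), Rtp4 (-0.90) and Xaf1 (-0.74), all still called. Xaf1 was not called after repeated quantile normalization (-1.06), Itga1 after centring on housekeeping genes (1.39), Kit with no filter on dim genes (adjusted p = 0.0513), and neither Xaf1 nor Itga1 in a fit on the NK arrays alone (adjusted p = 0.0613 and 0.102).

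Of 39 NK and lymphoid transcription factors, Nfil3 (1.47 ± 0.30), required for NK development, rose, and Tcf4 (-1.25 ± 0.28) and Hhex (-1.14 ± 0.29) fell (2 up and 4 down adjusted over the list alone, camera adjusted p = 0.743). Tbx21, which encodes T-bet, differed by -0.72 ± 0.28 (adjusted p = 0.232) and Id2 by -0.79 ± 0.46 (adjusted p = 0.539); both were chosen after their values were seen. Among 38 signal transduction genes Cd3g, Cd3d (2.88 ± 0.34) and the lipid phosphatase Inpp4b (3.10 ± 0.44) rose and Sh2b3 (-1.74 ± 0.32) was among 2 that fell (the same counts adjusted over the list alone, camera adjusted p = 0.526). Cd3e, another CD3 chain, differed by -0.08 ± 0.27 (adjusted p = 0.983) and was chosen after its values were seen. T lineage genes had 2 of 26 up, the same CD3 chains, and 4 down, including Il7r and Tespa1 (-2.13 ± 0.29, with the same counts adjusted over the list alone and camera adjusted p = 0.252). Single members fell among activation-induced genes (Icos, -1.52 ± 0.30, of 43; camera adjusted p = 0.52), glycolysis genes (Aldoc, -1.26 ± 0.32, of 19; adjusted p = 0.953) and dendritic and antigen presentation genes (Tcf4, of 18; adjusted p = 0.476), each also the single call adjusted over the list alone. Sox4 (1.92 ± 0.39) and Hoxa9 (1.83 ± 0.39) rose and Kit fell among 30 HSC and multipotent genes (3 up and 1 down adjusted over the list alone, adjusted p = 0.526). Early lymphoid genes had 1 of 24 up and 2 down (1 and 3 adjusted over the list alone, adjusted p = 0.476). B lineage genes had 1 of 27 up, Pou2af1 (2.41 ± 0.55), and 1 down (2 and 2 adjusted over the list alone, adjusted p = 0.838). Other innate lymphoid genes had 2 of 18 up and 2 down (3 and 3 adjusted over the list alone, adjusted p = 0.652). Besides the ETS family, limma called 0 members in 4 lists. At an unadjusted p below 0.05 there were 6 of 51 cell cycle genes (adjusted p = 0.177), 4 of 19 apoptosis genes (adjusted p = 0.869), 2 of 19 erythroid and megakaryocyte genes (adjusted p = 0.526, 1 down adjusted over the list alone) and 0 of 14 housekeeping genes (adjusted p = 0.252). Their largest differences were Ccne2 (1.18 ± 0.57), Cdc45 (1.11 ± 0.38), Cdkn1a (1.11 ± 0.60), Birc3 (-0.94 ± 0.36), Hemgn (-1.61 ± 0.45), Tfrc (1.02 ± 0.37), Snrpd3 (0.63 ± 0.42) and Psmb2 (0.52 ± 0.36).

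Several of these calls ended when 1 array was left out, which also lowers the precision, or when a gene's probe sets were averaged. Tcf4, Aldoc, Sox4 and Pou2af1 were not called without Ets1-deficient replicate 2 (-1.13, -0.95, 1.42 and 1.36), Ets1-present replicate 1 (-1.10, -1.12, 1.91 and 2.21) or Ets1-present replicate 2 (-1.39, -1.40, 1.93 and 2.61). Nfil3 and Hhex were not called without Ets1-deficient replicate 1 (1.43 and -0.78), Ets1-present replicate 1 (1.39 and -1.17) or Ets1-present replicate 2 (1.55 and -1.11). Hoxa9 lost its call without Ets1-deficient replicate 2 (1.32) or Ets1-present replicate 1 (1.19), Sh2b3 without Ets1-deficient replicate 2 (-1.51) or Ets1-present replicate 2 (-1.65), and Icos without Ets1-present replicate 1 (-1.44). The mean of a gene's probe sets ended the calls of Sox4 (0.37), Tcf4 (-0.39) and Hoxa9 (0.90), and gave smaller values, still called, for Inpp4b (1.96), Sh2b3 (-1.04), Aldoc (-0.82) and Icos (adjusted p = 0.00151). Kit was not called whichever array was left out. Without Ets1-present replicate 1 T lineage genes had 2 up and 2 down, and without Ets1-present replicate 2 or Ets1-deficient replicate 2 signal transduction genes had 3 up and 0 down. In a fit on the NK arrays alone Hoxa9 (adjusted p = 0.0702) and Pou2af1 (adjusted p = 0.0607) were not called, nor was Aldoc after repeated quantile normalization (-1.10). After centring on housekeeping genes Nfil3 was not called (1.23). The transcription factors then had 0 up and 4 down, signal transduction genes 3 and 1, HSC and multipotent genes 2 and 2, B lineage genes 1 and 3 and other innate lymphoid genes 1 and 3. Repeated quantile normalization gave transcription factors 2 up and 4 down, signal transduction genes 3 up and 1 down and B lineage genes 1 up and 2 down.

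Markers of myeloid cells moved with the genotype. Of 32 myeloid genes 10 were lower and 1 higher in Ets1-deficient NK arrays (18 down and 1 up adjusted over the list alone; camera adjusted p = 1.15e-07, and adjusted p = 0.0472 with an estimated correlation). Mpo, Ctsg (-2.45 ± 0.47), Prtn3 (-2.35 ± 0.37) and Ltf (-1.94 ± 0.32), all granule proteins of neutrophils and their precursors, fell most, and Fcgr3 is shared with the list of activating receptors. Without Ets1-present replicate 1, Ets1-present replicate 2 or Ets1-deficient replicate 2 the members down numbered 4, 4 and 3. Ctsg was not called without Ets1-deficient replicate 2 (-1.68) or Ets1-present replicate 1 (-2.42). The Y-linked gene Uty fell (-1.81 ± 0.28), while Xist, transcribed from the inactive X chromosome, had log2 levels of 8.65 and 9.08 in the Ets1-present and 9.78 and 9.48 in the Ets1-deficient arrays. Of 4 sex-linked genes Uty was the 1 called (also 1 adjusted over the list alone, camera adjusted p = 0.169). The Y-linked gene Eif2s3y, not called, was 8.735 and 8.511 in the Ets1-present and 7.817 and 7.555 in the Ets1-deficient arrays. Each NK array held Xist and Eif2s3y together at levels that no array of another population reached for both. The NK samples may therefore have mixed cells of both sexes. Whether the share of each sex differed between the genotypes was not tested. Actin 3' over 5' signal was 4.07 in Ets1-deficient replicate 2 and 2.86 in replicate 1.

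Of 334 NK identity genes, 34 were higher and 37 lower without Ets1, or 10.2% and 11.1%, where 1.59% and 2.23% of all genes were. This excess is partly built in and is no test. Genes high in 1 genotype alone could enter through the mean of both, and the selection favoured genes with a small error. The set as a whole did not pass camera (median -0.12, adjusted p = 0.285) or fry (adjusted p = 0.681). Its 5 leading genes were Gzma, Klre1, Klrb1a, Klrc1 and Klra16, of which Klra16 (-0.73 ± 0.19, adjusted p = 0.0353) was called. It lost its call whichever array was left out (-0.61 to -0.85), with the mean of its probe sets (-0.42), after centring on housekeeping genes (-0.97), with the stricter filter on dim genes (adjusted p = 0.0543) and without an intensity trend (adjusted p = 0.063). The 352 identity genes of CD4 T cells had 10 up and 41 down (median -0.21, camera adjusted p = 4.52e-06, and adjusted p = 0.0352 with an estimated correlation, fry adjusted p = 0.00257), Ltb and Slfn2 among those that fell. Leaving out Ets1-deficient replicate 2, Ets1-present replicate 1 or Ets1-present replicate 2 lowered the number of genes called between the genotypes from 514 to 314, 198 and 206. Centring on housekeeping genes shifted the median of all genes by -0.24 and gave 98 genes higher and 357 lower, and among NK identity genes 22 higher and 35 lower.

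From HSC to MPP, cell cycle genes rose and stem cell genes fell. Of 51 cell cycle genes 30 were higher in MPP and 21 did not pass (37 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.29e-35, and adjusted p = 0.0373 with an estimated correlation). Cep55 (4.23 ± 0.58), Ccna2 (3.74 ± 0.69) and Nusap1 (3.65 ± 0.57), all cell cycle genes, rose most overall. Of 30 HSC and multipotent genes 17 were lower and 13 did not pass (19 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.15e-15, and adjusted p = 0.0373 with an estimated correlation). They included the clotting factor Vwf (-4.19 ± 0.49), the cell cycle inhibitor Cdkn1c (-3.19 ± 0.25), Mllt3 (-3.04 ± 0.50) and Hoxb5 (-2.95 ± 0.32). Car1 (-5.26 ± 0.67) and Unc45b (-4.30 ± 0.22) fell most. In all 260 genes were higher and 538 lower (n = 2 per group). The split was 369 and 425 after repeated quantile normalization, which moved the median of all genes from -0.143 to -0.047. It was 305 and 217 after centring on housekeeping genes, which shifted the median of all genes by 0.21. Without MPP replicate 1, 220 genes were called, with 19 cell cycle genes up and 10 HSC and multipotent genes down, and without HSC replicate 1, 18 cell cycle genes were up. Without HSC replicate 1, Ccna2 was 1.92 and Nusap1 2.29, both called, and with the mean of their probe sets Cep55 was 2.22 and Nusap1 2.05. Ccna2, Nusap1 and Mllt3 were not called in a fit on the 4 compared arrays alone.

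MPP and LMPP differed in early lymphoid, erythroid and megakaryocyte, and stem cell genes, and several of these changes moved when 1 array was left out. Early lymphoid genes had 7 of 24 members up and 17 not passing (12 up adjusted over the list alone, camera adjusted p = 2.63e-13, and adjusted p = 0.00528 with an estimated correlation). Dntt (4.75 ± 0.38), the template-independent polymerase of V(D)J junctions, Ighm (5.03 ± 1.18), Satb1 (3.40 ± 0.27) and Notch1 (2.91 ± 0.31) rose. Of 30 HSC and multipotent genes 9 fell and 21 did not pass (12 down adjusted over the list alone, camera adjusted p = 1.1e-14, and adjusted p = 0.0221 with an estimated correlation). Those that fell included Vwf (-3.17 ± 0.49), Tek (-2.80 ± 0.54), Gata2 (-2.75 ± 0.39) and Fgd5 (-1.98 ± 0.37). Erythroid and megakaryocyte genes had 6 of 19 members down and 13 not passing (7 down adjusted over the list alone, camera adjusted p = 6.66e-11, and adjusted p = 0.021 with an estimated correlation). Cnn3 (4.63 ± 0.52) and Ccl3 (4.56 ± 0.50) also rose, and Slc18a2 (-4.82 ± 0.48), Apoe (-4.76 ± 0.47) and the mast cell protease Cpa3 (-4.65 ± 0.30) fell most. The counts were 127 higher and 104 lower (n = 2 per group), or 60 and 117 after centring on housekeeping genes, which shifted the median by -0.37. Leaving out LMPP replicate 1, LMPP replicate 2 or MPP replicate 2 gave 106, 106 and 104 called genes, with 3, 4 and 3 early lymphoid genes up and 5, 3 and 3 HSC and multipotent genes down. The median level of early lymphoid genes was 6.32 and 5.41 in LMPP arrays 1 and 2 against 5.48 and 5.32 in MPP arrays 1 and 2. That of erythroid and megakaryocyte genes was 5.33 and 7.11 in MPP arrays 1 and 2 against 4.64 and 4.84 in LMPP, and the median change of this list went from -0.71 to -0.17 without MPP replicate 2 and to -1.10 without MPP replicate 1. Ighm lost its call whichever array was left out (4.32 without MPP replicate 2) and with the mean of its probe sets (0.89) or every probe set on its own (adjusted p = 0.0502). Tek lost its call without LMPP replicate 1 (-2.69), LMPP replicate 2 (-2.92) or MPP replicate 2 (-1.40), and Fgd5 without LMPP replicate 2 (-1.50) or MPP replicate 2 (-1.55). Vwf was -1.82 without MPP replicate 2 and Tek -4.21 without MPP replicate 1, and neither was called in a fit on the 4 compared arrays alone (adjusted p = 0.0509 and 0.0928).

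In CLP, B lineage and early lymphoid genes were higher than in LMPP. Ebf1 (7.93 ± 0.34), a B lineage transcription factor, the recombinase gene Rag1 (6.77 ± 0.39) and Il7r (6.02 ± 0.40) rose most, and Blnk (4.78 ± 0.34) and Ly6d (3.46 ± 0.31) rose too. With the mean of its probe sets Ebf1 was 3.97. B lineage genes had 17 of 27 members up and 10 not passing (18 up adjusted over the list alone, camera adjusted p = 6.91e-18, and adjusted p = 0.00118 with an estimated correlation). Early lymphoid genes had 8 of 24 up and 2 down (the same adjusted over the list alone, adjusted p = 2.29e-07, and adjusted p = 0.0197 with an estimated correlation), and 20 up and 1 down after centring on housekeeping genes. Ccl3 (-6.92 ± 0.46), the neutrophil protease Prtn3 (-6.57 ± 0.34) and the immediate early gene Jun (-5.96 ± 0.32) fell most. Beside the actin ratios of CLP arrays 1 and 3, 30 of 51 cell cycle genes were lower and 1 higher (32 and 2 adjusted over the list alone, camera adjusted p = 6.08e-06, and adjusted p = 0.429 with an estimated correlation). That split was 15 lower and 17 higher after centring on housekeeping genes and 23 lower and 6 higher after repeated quantile normalization. Of 14 housekeeping genes 8 were lower (8 adjusted over the list alone, camera adjusted p = 0.00283, and adjusted p = 0.429 with an estimated correlation), with a median of -0.97 that turned to 0.12 after centring on these genes. In all 937 genes were higher and 2583 lower (n = 3 CLP, n = 2 LMPP). The split was 1606 and 2104 after repeated quantile normalization, which moved the median from -0.078 to 0.007. After centring on housekeeping genes, which shifted the median by 1.09, it was 8140 and 512. With CLP array 2 alone, a setting chosen after seeing the data, it was 566 and 664. Without LMPP replicate 1 or LMPP replicate 2, 1621 and 1579 genes were called.

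Myeloid genes were higher in GMP than in LMPP. Actin 3' over 5' signal differed too, at 6.44 to 6.68 in the GMP and 1.92 to 2.10 in the LMPP arrays. Of 32 myeloid genes tested, 27 were higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 7.07e-19, and adjusted p = 0.00321 with an estimated correlation). The largest were Ms4a3 (7.32 ± 0.38), the calprotectin subunit S100a8 (7.20 ± 0.42), Igsf6 (6.39 ± 0.24) and haptoglobin, Hp (6.14 ± 0.28). Sgms2 (6.83 ± 0.20), a sphingomyelin synthase, rose as well. Early lymphoid genes had 14 of 24 members down and 10 not passing (15 down adjusted over the list alone, camera adjusted p = 1.53e-08, and adjusted p = 0.0177 with an estimated correlation). Among them were Dntt (-8.04 ± 0.35), Flt3 (-4.59 ± 0.39), Cd27 (-4.17 ± 0.29) and Ccr9 (-2.14 ± 0.41). Ccl3 (-7.45 ± 0.46) and Egr1 (-6.87 ± 0.51) also fell. In all 2150 genes were higher and 1750 lower (n = 3 GMP, n = 2 LMPP). Without LMPP replicate 1 or LMPP replicate 2, 2273 and 2391 genes were called and Ccr9 was -1.06 and -3.21, and it was -0.71 with the mean of its probe sets.

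The myeloid and lymphoid progenitors were also compared directly, with actin 3' over 5' signal of 6.44 to 6.68 in GMP and 3.26 to 5.27 in CLP. GMP exceeded CLP in 29 of 32 myeloid genes, with 3 not passing (the same adjusted over the list alone, camera adjusted p = 9.51e-18, and adjusted p = 0.00139 with an estimated correlation), or 21 higher and 3 lower after centring on housekeeping genes. Examples were Prtn3 (8.70 ± 0.30), the factor XIII subunit F13a1 (7.72 ± 0.40), Ctsg (7.39 ± 0.39) and Ms4a3 (7.05 ± 0.34). Early lymphoid genes were lower for 20 of 24 members and higher for 1 (21 and 1 adjusted over the list alone, camera adjusted p = 3.15e-16, and adjusted p = 0.00136 with an estimated correlation). Dntt (-8.85 ± 0.31), Il7r (-7.65 ± 0.35), Rag1 (-7.35 ± 0.35), Blnk (-5.78 ± 0.30) and Ebf1 (-8.11 ± 0.30, or -4.15 with the mean of its probe sets) were lower. In all 4176 genes were higher and 2437 lower in GMP (n = 3 per group). The split was 3175 and 2954 after repeated quantile normalization, which moved the median from 0.087 to -0.047. It was 1289 and 8255 after centring on housekeeping genes, which shifted the median by -1.08. With CLP array 2 alone, 1799 were higher and 1084 lower.

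**Figure D3:**
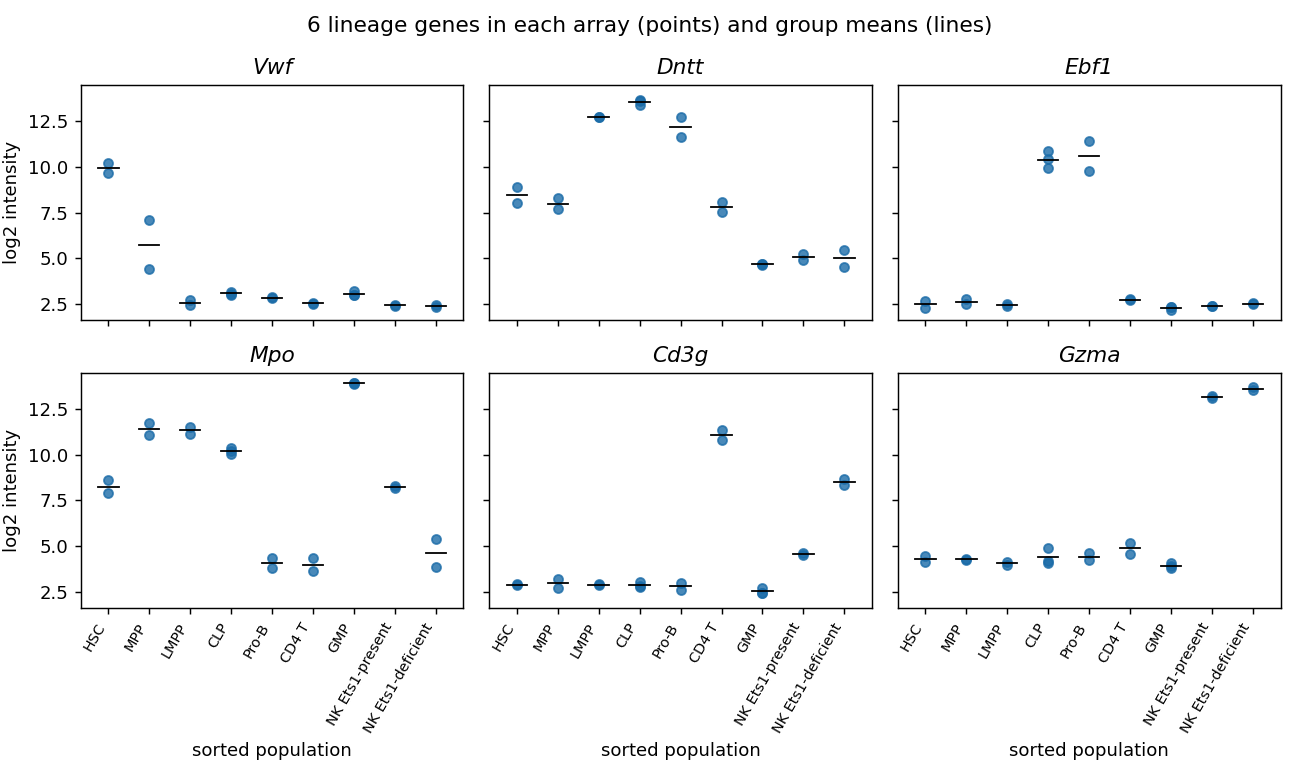
Log2 intensity of 6 genes in each sorted population; points are arrays and lines are group means. Vwf was highest in HSC, Dntt in CLP, Ebf1 in CLP and pro-B cells, Mpo in GMP, Cd3g in CD4 T cells and Gzma in NK cells, with Cd3g higher and Mpo lower in Ets1-deficient than in Ets1-present NK cells.

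Pro-B cells were set against CLP for B lineage and early lymphoid genes. Actin 3' over 5' signal was 2.07 and 3.11 in pro-B arrays 1 and 2 and 3.26 to 5.27 in CLP, and pro-B array 1 had a mean intensity of 117 and a maximum of 12738, against 160 and 22239 in array 2. Of 27 B lineage genes 17 were higher and 2 lower than in CLP (18 and 3 adjusted over the list alone, camera adjusted p = 4.02e-07, and adjusted p = 0.0542 with an estimated correlation), or 14 and 6 after centring on housekeeping genes. They included the coactivator Pou2af1 (4.98 ± 0.50), the surrogate light chain gene Igll1 (4.47 ± 0.30), Cd22 (4.37 ± 0.31) and Ms4a1 (3.74 ± 0.24), which encodes CD20. With the mean of their probe sets Igll1 was 2.65, Cd22 2.79 and Ccr9 -1.41. Jchain (8.43 ± 0.34), which links secreted immunoglobulin, Enpep (5.53 ± 0.23) and Xist (5.51 ± 0.37) rose most apart from immunoglobulin genes, and Mpo (-6.13 ± 0.37), Mn1 (-5.72 ± 0.30) and the progenitor antigen Cd34 (-5.47 ± 0.41) fell most. Xist lay between 9.87 and 10.73 in the pro-B and CD4 T arrays and between 3.81 and 5.38 in the HSC, MPP, LMPP, CLP and GMP arrays, and the Y-linked gene Eif2s3y between 2.49 and 2.73 against 5.63 and 8.88, so sex-linked transcripts changed with the population. Early lymphoid genes had 13 of 24 members down, such as Ccr9 (-4.91 ± 0.41) and Flt3 (-4.72 ± 0.39), and 4 up, such as Spib (4.19 ± 0.23; 14 down and 5 up adjusted over the list alone, camera adjusted p = 0.00401, and adjusted p = 0.145 with an estimated correlation), or 16 down and 2 up after centring on housekeeping genes. In all 2841 genes were higher and 1887 lower (n = 2 pro-B, n = 3 CLP). The split was 859 and 8379 after centring on housekeeping genes, which shifted the median by -1.03, and 1223 and 1233 with CLP array 2 alone. Repeated quantile normalization moved the median from -0.015 to -0.046 and gave 2517 higher and 2402 lower. Without pro-B replicate 2, 3067 genes were called, and with array 2 alone in both groups, also chosen after seeing the data, 2555.

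Actin 3' over 5' signal was 0.98 and 1.23 in CD4 T cells and 3.26 to 5.27 in CLP. CD4 T cells were set apart from CLP by T lineage genes, of which 22 of 26 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 1.83e-15, and adjusted p = 0.000115 with an estimated correlation). Cd3g (8.18 ± 0.22), the transcription factor Bcl11b (7.85 ± 0.38), Cd3d (7.56 ± 0.31) and Thy1 (7.30 ± 0.29) rose, as did Ms4a4b (8.30 ± 0.32). Early lymphoid genes divided, with 12 of 24 down, such as Rag1 (-7.24 ± 0.39) and Bcl11a (-5.91 ± 0.31), and 5 up, such as the migration receptors Gpr183 (7.11 ± 0.35) and Ccr7 (6.83 ± 0.34; the same counts adjusted over the list alone, camera adjusted p = 0.00312, and adjusted p = 0.144 with an estimated correlation), or 17 down and 4 up after centring on housekeeping genes. Cd93 (-8.07 ± 0.23), Hoxa9 (-7.79 ± 0.35) and Ebf1 (-7.65 ± 0.34) fell most. These were -3.91, -4.77 and -3.97 with the mean of their probe sets, and Bcl11a was -3.09. In all 3915 genes were higher and 2654 lower (n = 2 CD4 T, n = 3 CLP). The split was 2892 and 3284 after repeated quantile normalization, which moved the median from 0.054 to -0.102. It was 1394 and 7782 after centring on housekeeping genes, which shifted the median by -1.04. With CLP array 2 alone, 2319 were higher and 1736 lower.

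Ets1-present NK cells exceeded CLP in all 15 activating receptor genes tested, in 10 of 13 inhibitory receptor genes, with 2 lower, and in 18 of 24 cytotoxic effector genes. Adjusted over the list alone the numbers were 15, 10 with 2 lower, and 19 with 1 lower. The effectors had 16 higher and 2 lower after centring on housekeeping genes. These lists passed camera at adjusted p = 1.21e-13, 1.07e-05 and 3.76e-10, and at adjusted p = 0.000497, 0.00208 and 0.000529 with an estimated correlation. The granzyme Gzma (8.75 ± 0.27) and the chemokine Ccl5 (8.47 ± 0.32) rose most, with Ms4a4b (8.23 ± 0.32), and the effectors Serpinb6b (6.86 ± 0.38) and perforin, Prf1 (6.62 ± 0.28), rose with them. Among receptors, Klre1 (8.12 ± 0.21), Klrb1a (7.75 ± 0.21), Klrc1 (7.35 ± 0.21), Fcgr3 (6.69 ± 0.28), Klrd1 (6.50 ± 0.34), Ncr1 (5.79 ± 0.34), Crtam (5.63 ± 0.38) and Klra17 (5.49 ± 0.26) were higher. The NK transcription factors Tbx21 (7.36 ± 0.26), Ikzf3 (7.04 ± 0.27), Id2 (6.42 ± 0.42) and Eomes (6.15 ± 0.24) rose within a list that had 19 of 39 up and 5 down (19 and 6 adjusted over the list alone, camera adjusted p = 0.00768, and adjusted p = 0.25 with an estimated correlation) and whose median turned from 0.66 to -0.03 after centring on housekeeping genes. The list then had 14 up and 9 down, and 16 up and 9 down after repeated quantile normalization. Dntt (-8.47 ± 0.35), Bex6 (-7.99 ± 0.41), Ebf1 (-7.99 ± 0.34), Rag1 (-7.19 ± 0.39), Flt3 (-6.92 ± 0.39) and Bcl11a (-6.73 ± 0.31) fell. With the mean of their probe sets Ms4a4b was 5.18, Klrc1 4.15, Prf1 3.47, Ikzf3 3.55, Id2 3.83, Bcl11a -3.20 and Ebf1 -4.16. Myeloid genes, among them Fcgr3 of the receptors above, were higher for 17 of 32 members and lower for 5 (18 and 5 adjusted over the list alone, camera adjusted p = 0.00369, and adjusted p = 0.192 with an estimated correlation). The split was 12 and 7 after centring on housekeeping genes and 15 and 6 after repeated quantile normalization. Myeloid members above background had a mean log2 level of 8.56 and 8.60 in these NK arrays against 5.80 to 6.04 in CLP. In all 4364 genes were higher and 2588 lower (n = 2 NK, n = 3 CLP). The split was 3043 and 3293 after repeated quantile normalization, which moved the median from 0.166 to -0.070. It was 2160 and 5161 after centring on housekeeping genes, which shifted the median by -0.69. Actin 3' over 5' signal was 2.76 and 2.90 in these NK arrays and 3.26 to 5.27 in CLP, and Xist 8.65 and 9.08 against 3.84 to 5.38. Cell type, strain and Rag2 genotype, with sex-linked transcripts, changed together here and in the comparison with CD4 T cells and cannot be told apart.

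NK and CD4 T cells differed in receptors, effectors and T cell genes. Eif2s3y, which is Y-linked, was 8.74 and 8.51 in the NK and 2.51 and 2.73 in the CD4 T arrays, and actin 3' over 5' signal 2.90 and 2.76 against 0.98 and 1.23. Gzma (8.26 ± 0.30), Klre1 (8.15 ± 0.23), Klrb1a (7.69 ± 0.23), Cd244a (7.12 ± 0.43), Klrc1 (7.06 ± 0.23, or 4.14 with the mean of its probe sets), Ncr1 (6.10 ± 0.37), Fcgr3 (6.01 ± 0.30), Xcl1 (5.98 ± 0.26), Klra17 (5.25 ± 0.29), Ccl3 (5.09 ± 0.50) and Nkg7 (4.53 ± 0.33) were higher in NK cells. Activating receptors had 11 of 15 members higher and 1 lower, inhibitory receptors 7 of 13 and 4, and cytotoxic effectors 16 of 24 and 2. Adjusted over the list alone these were 11 and 1, 7 and 4, and 16 and 3. The lists passed camera at adjusted p = 1e-11, 0.00465 and 4.15e-10, and at adjusted p = 0.000436, 0.0213 and 0.000436 with an estimated correlation. T lineage genes were lower for 23 of 26 members, with 3 not passing (the same adjusted over the list alone, camera adjusted p = 2.76e-28, and adjusted p = 5.52e-06 with an estimated correlation). The largest falls of this list were in Cd5 (-8.27 ± 0.26), Ccr7 (-7.20 ± 0.37), Cd3g (-6.49 ± 0.25) and Cd3d (-6.14 ± 0.34). St6gal1 (-7.84 ± 0.55, or -3.86 with the mean of its probe sets), Btla (-7.23 ± 0.57) and Ctla4 (-5.02 ± 0.27) were lower too. Among transcription factors, Eomes (4.58 ± 0.26) and Tbx21 (4.23 ± 0.28) were higher and Bcl11b (-5.13 ± 0.42) and Id3 (-4.17 ± 0.35) lower. Myeloid genes were higher for 19 of 32 members and lower for 1 (20 and 1 adjusted over the list alone, camera adjusted p = 2.72e-12, and adjusted p = 0.00527 with an estimated correlation), with S100a8 (7.71 ± 0.47) among the largest rises of the comparison and Fcgr3 a member of this list too. In all 1921 genes were higher and 1381 lower (n = 2 per group), or 2881 and 761 after centring on housekeeping genes, which shifted the median by 0.35. Leaving out NK replicate 1, NK replicate 2 or CD4 T replicate 2 gave 1985, 2085 and 2156 called genes.

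Each population was also described by genes that exceeded all other populations. HSC had 178 such genes, led by Unc45b, Vwf, Sult1a1, Car1 and Cdkn1c, and MPP had 1, Mdga1. LMPP had 11, led by Ccl3, Ddx4, Wfdc17, Il1r1 and Msrb3, and CLP had 50, led by Slc27a2, Cass4, Stum, Chst15 and Camk1d. GMP had 273, led by Sgms2, Igsf6, Ms4a3, Met and Mgam, and pro-B cells had 120, led by Tmem255a, Igll1, Il33, Enpep and Jchain. CD4 T cells had 352, led by Cd5, Gpr183, Slfn1, Ifit1bl1 and Ccr7, and NK cells 334. Together these were 1319 genes, and 2044 after centring on housekeeping genes. In the NK set cell type cannot be told apart from strain and Rag2 genotype.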

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

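The settings with CLP array 2 as the single CLP array, and with ProB array 2 as the single ProB array, were chosen after seeing the data; the others were planned. No called gene named by the fixed rule changed sign under the alternatives run for its comparison. For the NK genotypes, 942 of 1062 values of 71 named genes kept direction and side of the threshold, 88 were no longer called, 31 became called and 1, of the uncalled Snrpd3, changed sign with the mean of its probe sets. Over all comparisons, averaging a gene's probe sets made 47 of 180 called values of named genes over 1.5 times smaller and ended 8 calls. The number of genes called between the NK genotypes was 514, against 840 with every probe set on its own. With array weights it was 1778, and 7529 for GMP against LMPP, 5280 for NK against CD4 T cells, 468 for LMPP against MPP and 464 for MPP against HSC. With only the compared arrays, which changes the pooled error, it was 1259, and 101 for MPP against HSC, 551 for CLP against LMPP, 7522 for GMP against LMPP, 1584 for pro-B, 3580 for CD4 T and 4290 for NK against CLP, and 5032 for NK against CD4 T cells. Centring on housekeeping genes gave 522 for MPP against HSC, 8652 for CLP against LMPP, 9238 for pro-B against CLP and 2044 identity genes, where 1319 were found. With a 2-fold minimum 4078 genes were called between GMP and CLP. CLP array 2 alone gave 1230 genes against LMPP, and 2883 for GMP, 2456 for pro-B (2555 with ProB array 2 alone), 4055 for CD4 T and 4367 for NK cells. Of the fixed lists 5 were called between the NK genotypes, 2 with an estimated correlation and 8 with only the NK arrays. Where not stated otherwise the cause was not tested.

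Leaving out each replicate gave 198 to 344 genes between the NK genotypes, 220 to 774 for MPP against HSC, 104 to 206 for LMPP against MPP, 1579 to 5222 for CLP and 2273 to 3232 for GMP against LMPP, 3067 to 6183 for pro-B against CLP and 1985 to 2479 for NK against CD4 T cells. A lone remaining sample was assumed to vary like the other groups. Calls can end in these fits through the lost precision alone. The replicate block over all arrays kept every count within 1.5 times, with 531 for the NK genotypes, and in the NK arrays alone the replicate block gave 1348, where the compared arrays without it gave 1259. Same-numbered arrays deviated with correlations from -0.18 to 0.37, and the numbers were not taken to pair the samples. The highest, 0.37, was between MPP and HSC, where a shared replicate effect cannot be excluded. Among GMP and CLP arrays, the only groups with 3 numbers, the correlations were -0.18, 0.05 and 0.24. Dim genes may have been limited by signal over background, which was not tested. Mean intensity was low in CLP arrays 1 and 3 (113 and 107 against 149 in CLP array 2) and in pro-B array 1 (117).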

Other observations

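Some gene groups moved outside the populations that the lists were meant to mark, and the genes named in this paragraph were chosen after their values were seen. Immediate early and activation genes were lower in GMP than in LMPP for 32 of 43 members and higher for 2 (33 and 3 adjusted over the list alone), with Egr1 (-6.87 ± 0.51, SE), Zfp36 (-6.61 ± 0.36) and Fosb (-5.94 ± 0.39) among them (camera adjusted p = 1.5e-17, and adjusted p = 0.0492 with an estimated correlation). In CLP 28 of the 43 were lower and 3 higher than in LMPP (30 and 3 adjusted over the list alone), with Jun, Fosb (-5.54 ± 0.39) and Dusp1 (-5.25 ± 0.33) falling (camera adjusted p = 9.65e-10, and adjusted p = 0.22 with an estimated correlation). After centring on housekeeping genes 19 were lower and 11 higher, and the actin 3' over 5' signal of CLP arrays 1 and 3 stood apart, as that of GMP did from LMPP. Ets1-present NK cells exceeded CD4 T cells in 41 of 51 cell cycle genes, with 10 not passing (43 higher adjusted over the list alone) and Hmmr (4.86 ± 0.50), Aurkb (4.84 ± 0.51) and Ccne2 (4.84 ± 0.57) rising (camera adjusted p = 9.07e-24, and adjusted p = 0.0289 with an estimated correlation). Interferon-stimulated genes were lower in NK than in CD4 T cells for 20 of 31 members, with 11 not passing (24 lower adjusted over the list alone) and Ifi27l2a (-5.74 ± 0.38), Rsad2 (-5.43 ± 0.45) and Isg20 (-3.91 ± 0.32) falling (camera adjusted p = 3.23e-12, and adjusted p = 0.0213 with an estimated correlation).

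The test of genes near Ets1 was chosen only after the number of changed genes had been seen, as was the threshold above background for the myeloid genes. The predictions of the other tests were written after a first look at leading genes, counts and array intensities, though before the test values.

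For the myeloid genes lower in Ets1-deficient NK cells, fewer myeloid cells in those sorts predicted a median change of -1 or lower over list members well above background. Over the 21 members at least 1 log2 unit above the array median it was -1.33 (95% bootstrap interval over members -1.39 to -1.04), with the same value at 2 log2 units. Over the 14 at least 3 log2 units above the array median it was -1.29 (-1.47 to -0.78). With dimmer members it was -0.77 (-1.28 to -0.10) over all 32 and -0.91 (-1.34 to -0.10) over the 30 above the array median. No threshold had been set before the values were seen, so fewer myeloid cells may be a source but this stays open. These intervals resample genes measured on the same arrays, so they do not measure the spread between arrays. The mean of the 21 was 7.71 and 7.08 in the Ets1-deficient and 8.56 and 8.60 in the Ets1-present arrays. Of these members 18 were lower, while Irf8 (0.433), Gfi1 (0.415) and Ly86 (0.218) were higher but not called. Fcgr3 and Nkg7 among the 21 are also NK genes. The abundant S100a8 (-1.47, adjusted p = 0.0982), Ngp (-1.37, adjusted p = 0.19) and S100a9 (-1.35, adjusted p = 0.124) lay near the median change but were not called. A change within NK cells that follows Ets1 stays open and untested. Of the 200 tested genes nearest to Ets1 in gene order 4.50% were called against 3.80% of the others, an odds ratio of 1.19 (95% interval 0.53 to 2.33, Fisher's exact test, 2-sided p = 0.575), too wide to exclude a flanking segment of another strain behind some calls.

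In CLP 73.4% of the genes called against LMPP were lower. Weaker amplification or RNA quality of CLP arrays 1 and 3 predicted a drop of this share with CLP array 2 alone. The drop passed the bound set before the test values. With CLP array 2 as the only CLP array the share was 54.0%, but this also left no replicate in the CLP group. Repeated quantile normalization, with all CLP arrays kept, took the share to 56.7%, so such a drop is not particular to leaving out arrays 1 and 3. Leaving out array 1 or array 3 alone gave 72.0% and 70.0%, but each of these fits kept the other of the 2 arrays and so cannot speak against them. In GMP, where actin 3' over 5' signal was higher still, 44.9% of the genes called against LMPP were lower. Mean intensity was 147 to 162 in the GMP arrays, against 113 and 107 in CLP arrays 1 and 3. GMP therefore does not match these CLP arrays. Because the fit on array 2 also lost the replicates and the quantile step gave a like drop, the part of RNA quality or amplification of CLP arrays 1 and 3 stays open. Centring on housekeeping genes took it to 5.92%, but this moved every gene by the same 1.09 and the housekeeping genes were themselves lower in CLP, so it decides nothing and the part of the scaling stays open. A lower RNA content of CLP as a biological difference was not tested.

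Jchain and the immunoglobulin constant genes Igha (7.24 ± 0.37) and Ighg3 (5.11 ± 0.28) were higher in pro-B cells than in CLP, the last 2 chosen after their values were seen. Plasma cells in the pro-B sorts were predicted to give a list of 15 plasma cell genes a median change of at least 1, with most members called higher. The median was 0.71 (95% bootstrap interval over list genes 0.09 to 2.81, which does not measure the spread between arrays). Of the 15 genes 8 were called higher, so this part of the prediction was met, while the median lay below its bound. The plasma cell genes Sdc1 (-0.02) and Prdm1 (-0.19) were not called. Irf4 (3.56), Mzb1 (3.75) and Slamf7 (3.51) rose, and Irf4 is also expressed by B lineage cells. A few plasma cells therefore could not be excluded, and expression in the pro-B cells themselves stays open.

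For GMP against CLP, the 6 arrays allow 10 splits, too few for a share under 0.05. The real split called 6613 genes, as many as 1 of the 10, and the highest of the others called 0 by limma at the same threshold. Every other split placed arrays of both populations in each group, so the difference between the populations entered the error. The 0 calls were therefore to be expected and say nothing about chance.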
